A study of Phaeodactylum tricornutum with 53 samples.

How the data were processed

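Cultures of Phaeodactylum tricornutum Wt and of the bHLH1a-overexpressing line OE-1 were kept at 18 °C under 40 µmol photons per m2 per s in 16 h of light and 8 h of dark, per the labels, and sampled in darkness. Cells from 100 ml of culture were filtered and total RNA was extracted and hybridised, unlabelled, with biotin- and fluorescence-tagged probes, per the labels' protocols. The replicates are described in the labels as separate cultures, 3 per line, and a replicate number taken from the labels was used as the culture.

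The authors deposited a signal per probe and sample in 6 tables, 1 per culture, which the labels call raw data. These deposited signal values are not whole numbers: 13 of 1060 are whole, and 7 equal 1, which is the lowest value. How they were scaled or corrected for background is not given in the sources used here, so counting depth is unknown and no counting interval is given. The authors also deposited a value table on the log2 scale. Recomputing the log2 of each signal over the geometric mean of Actin12, Rps and Tbp in the same sample gave those values within 5.00e-10, which identifies the scale and the row names of the 3 bHLH1a probes. No other columns were used.

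Because the signals are not counts, the count test fixed before the data were examined could not be run, nor could the alternatives built on count models. The test fixed for that case was used: signal was divided by the geometric mean of the 3 reference genes, rescaled to a geometric mean of 1 over samples, and log2(value + 1) was tested with limma 3.58.1 in R 4.3.3. Fold changes are on that scale, and the pseudocount of 1 understates the change of low signals. All 17 target probes entered each fit and each Benjamini-Hochberg adjustment, with an adjusted p threshold of 0.05, two-sided. Counts are over 15 genes, with bHLH1a counted by its endogenous probe and its total and transgene probes not counted further.

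For the level over the dark period, signals and references were averaged per culture over the 8 time points from 4 to 25 h that all 6 cultures have, and 3 cultures were compared with 3. Time courses, differences at each time and 25 h against 1 h came from a fit with a mean for each line and time, with 35 residual degrees of freedom. The cosine fit had an intercept, a cosine and a sine of 24 h per line. These fits treat the samples of a culture as independent. Amplitudes per culture were compared by an exact two-sided permutation test, which cannot go below 0.1. Gene groups were set by the start of the gene name: 10 transcription factors, 3 cell cycle genes, 1 pigment synthesis gene and 1 other, Vdr, while no photoreceptor or light-harvesting gene was in the panel. The rule for named genes was that every gene is named, with full statistics for bHLH1a and up to 6 genes per comparison with the smallest adjusted p.

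The fits were tested on 100 simulated datasets of 15 genes, 9 of them unchanged, with the real deviations of whole cultures. These were drawn for each gene separately and with random sign, so deviations that genes share within a culture were not kept. Profiles drawn from Wt replicate 3, which has no 1 h sample, carried no deviation at 1 h. Rates for 25 h against 1 h can therefore look better than they are. Levels were simulated on profiles flat over time, so their rates need not hold for levels that rest on a few times of high signal. A log2 level difference of 1 was recovered in 77.3% of genes and of 2 in 98.7%, with 4.00% of unchanged genes called. A difference of 2 present at all times was recovered in 80.7% when tested at 13 h only, adjusted over the 15 genes. In that test 6.00% of unchanged genes were called and 14.2% of all calls were false. The reported gene and time pairs were adjusted over all probes and times together, so these shares need not hold for them. For the difference in time course, an added cosine of amplitude 1 was recovered in 53.0% and of 2 in 97.3%, with 9.56% of unchanged genes called. For the difference in cosine these were 83.0% and 100%, with 12.6% of unchanged genes called. For the time course within a line, unchanged genes were called in 7.22% in Wt and 6.78% in OE-1, and for the cosine within a line in 13.0% and 12.4%. A difference of 2 in the 25 h against 1 h change was recovered in 40.3%, with 1.78% of unchanged genes called and 10.2% of all calls false.

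Alternatives were the authors' log2 values, the total of the target probes or the median of ratios as scale, each reference gene left out, minimum mean signals of 20 and 100, a pseudocount of 10, replicate blocks, other time points, periods of 21 and 27 h, a linear trend and each culture left out. Scaling without the reference genes and a background floor, which raised target signals to the highest Wt transgene signal, were added after the data were seen, singly and together. Some choices were also changed after first results had been seen. The background floor had at first been applied to the reference genes too, which called more genes in level, and was limited to target probes so that a single choice moves. The block for cultures was recoded to sum to 0 within a line, peak times under other periods were computed with that period, and for the total and transgene probes, which had no called cosine in OE-1 and in Wt respectively, the amplitude difference replaced the peak time. Of the 15 symbols, 4 matched the gene table of assembly ASM15095v2: CYCB1 (PHATRDRAFT_46095), CYCH1 (PHATR_36892), dsCYC2 (PHATRDRAFT_34956) and Vdr (PHATRDRAFT_56450). The build used for the probes is not given in the sources used here, so no coordinates are given.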

Results

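The series followed 15 selected genes of the marine diatom Phaeodactylum tricornutum through 24 h of continuous darkness in the wild type (Wt) and in OE-1, a line that overexpresses bHLH1a. The series title names this bHLH-PAS protein RITMO1 and places it in the control of daily rhythms. Cultures had been entrained to 16 h of light and 8 h of dark for 2 weeks and were then sampled in darkness every 3 h, from 1 to 25 h after the light would have come on. Each line had 3 cultures, called replicates here. The analysis covers 53 samples, 26 of Wt and 27 of OE-1, and the 1 h sample of Wt replicate 3 is not analysed here. Total RNA was hybridised with tagged gene-specific probes, and the summed signal of the 20 probes ranged from 5566 to 27854 per sample, with a median of 11941. Wt cells lack the transgene, so the transgene probe in Wt was taken as the background, with a median of 5.20 and a highest value of 31.6. That value came from Wt replicate 2 at 7 h, where the total probe read 199 and the endogenous probe 2.92, so it may not be background alone. Wt replicate 1 read 30.0 at 19 h, and the other Wt values were 15.3 or less. The background floor and the statements on background below use 31.6, from a single probe and sample, and may set background too high. The panel had been picked by the authors for its expression profiles in an earlier screen, so a high share of genes with a time course is not independent evidence about the genome.

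bHLH1a itself was examined first, with a probe for the endogenous transcript, a probe for the transgene and a probe for their total. The transgene was high in OE-1 at the start and fell through the dark period. Its mean signal was 548 ± 266 (SD, n = 3) at 1 h and 328 ± 66.4 (SD, n = 3) at 4 h, and 15.5 ± 4.22 (SD, n = 3) at 25 h, where Wt background was 10.5 ± 2.08 (SD, n = 3). On the log2 normalized scale OE-1 lay above Wt by 7.88 at 1 h (SE 0.83, adjusted p = 1.58e-10), and all 3 OE-1 cultures exceeded the highest Wt background at 1, 4 and 7 h. From 10 h on not all of them did, and at 16 h none did, so the differences called at 10, 13 and 16 h lay partly or wholly within background and were not called with signals raised to it. Because Wt was at background, these differences are not folds over a Wt transcript. The total probe exceeded Wt by 6.43 at 1 h (SE 0.68), 6.62 at 4 h (SE 0.61) and 3.55 at 7 h (SE 0.61, adjusted p = 1.32e-05), where most Wt signals were also within background, and with signals raised to it by 5.62, 6.07 and 3.04. It was not called from 10 h on, and its mean signal in OE-1 was 901 at 1 h, 326 at 7 h and 348 at 25 h.

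Endogenous bHLH1a rose in darkness in both lines, from a signal of 4.26 ± 4.12 (SD, n = 2) at 1 h to 280 ± 80.1 (SD, n = 3) at 16 h in Wt, and from 8.03 ± 3.09 to 286 ± 135 (SD, n = 3) in OE-1. Over 4 to 25 h the endogenous probe differed between the lines by 0.12 on the log2 scale (SE 0.20, 95% interval -0.32 to 0.56, adjusted p = 0.605), which is within the spread between cultures. The transgene probe differed by 3.15 (SE 0.27, adjusted p = 9.11e-06), or 1.498 with signals raised to the highest Wt background, and the total probe by 0.49 (SE 0.22, adjusted p = 0.104), the latter not past the threshold. The total probe passed it over 1 to 22 h, with 1.09 (adjusted p = 0.0179), a setting that adds the 1 h samples and also leaves out 25 h, and when every time weighed the same, with 0.97 (adjusted p = 0.0083). Over 1 to 22 h Wt replicate 3 entered without a 1 h sample, so the cultures were not averaged over the same times.

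**Figure D1:**
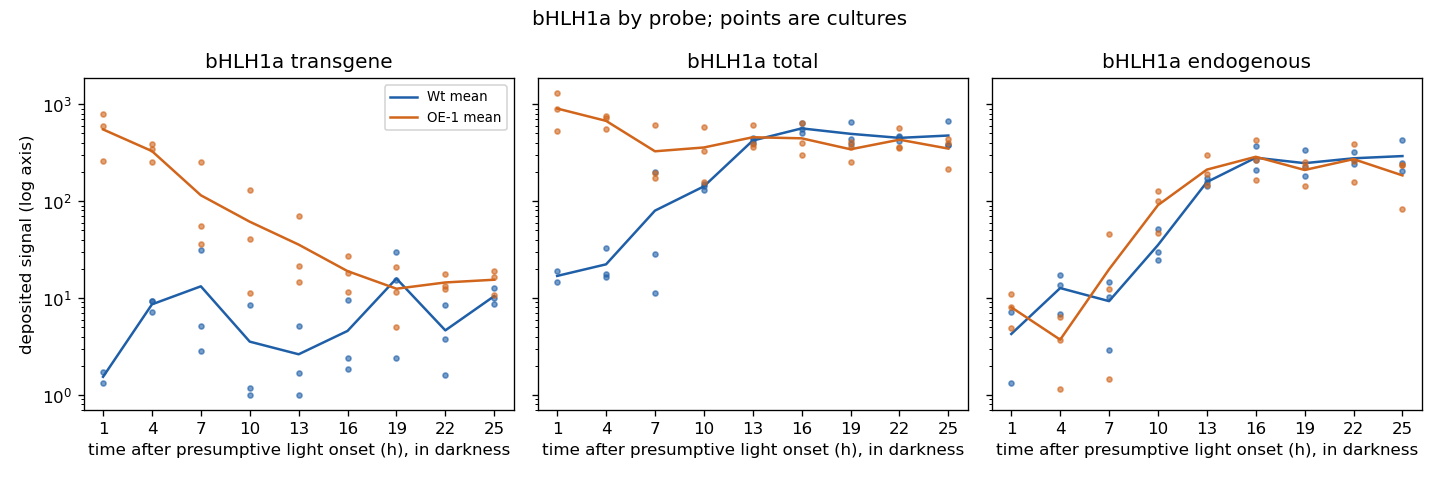
Signal of the 3 bHLH1a probes on a log axis against hours after the light would have come on, with points for cultures and lines for group means of Wt and OE-1. Transgene signal in OE-1 falls from a mean of 548 at 1 h to 15.5 at 25 h, while the endogenous signal rises in both lines.

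The mean level over 4 to 25 h differed in 5 of the 15 genes. It averages signals, so times of high signal weigh most and a shift in timing can enter it. The same 5 genes were called as a mean of log2 values, in which every time weighs the same. HSF3.3a, a heat shock factor family member, was higher in OE-1 by 2.22 on the log2 scale (SE 0.43, adjusted p = 0.0027), a 4.67-fold difference, with culture means of 5.15 ± 0.06 (SD, n = 3) in Wt and 7.37 ± 1.06 (SD, n = 3) in OE-1. Its highest OE-1 mean signals, 566 at 22 h and 460 at 25 h, weigh most in this value. In Wt replicate 1 it read 217 at 19 h and at most 38.0 at the other times from 4 to 25 h. The small Wt SD therefore does not mean that the Wt cultures had like profiles. The other called genes were lower in OE-1. dsCYC2, the diatom-specific cyclin tied to light-dependent onset of cell division, was lower by a log2 difference of -1.96 (SE 0.20, adjusted p = 2.58e-05), from 5.70 ± 0.28 to 3.74 ± 0.02 (SD, n = 3 each). Its mean signal at 4 h was 301 in Wt and 13.2 in OE-1, and at later times at most 31.0 in Wt. This difference therefore rests mainly on 4 h, and an earlier fall in OE-1 could give it. The close bHLH1a relative bHLH1b differed by -0.98 (SE 0.20, adjusted p = 0.0028) and Vdr, a violaxanthin de-epoxidase-related gene, by -1.01 (SE 0.23, adjusted p = 0.0052). CYCB1, a B-type cyclin, differed by -1.29 (SE 0.45, adjusted p = 0.0491). In each of these genes the 3 cultures of OE-1 lay entirely above or below the 3 of Wt, which chance gives in 10% of genes, and the exact two-sided permutation test gave p = 0.1, its smallest possible value.

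By group, 2 of the 10 transcription factors differed in level, HSF3.3a upward and bHLH1b downward, and 2 of the 3 cell cycle genes were lower, dsCYC2 and CYCB1. The third cyclin, CYCH1, had a difference of -0.12 (SE 0.19). Por2, a protochlorophyllide oxidoreductase of chlorophyll synthesis and the pigment gene of the panel, had -0.24 (SE 0.24). Adjusted over the list alone, 4 of the 15 genes were called, and CYCB1 was not among them. Among genes not called, HSF1d had 0.67 (SE 0.26, adjusted p = 0.0683) and was called on the total, on the median of ratios, without Tbp and without OE-1 replicate 1 or 2 (0.77 to 0.93). Myb1R had -0.43 and was called on the authors' values (-0.96), without Actin12 (-0.70) and without OE-1 replicate 3 (-0.65). The others had bZIP5 -0.35, HSF4.7b -0.34, bZIP7 -0.29, HSF1g 0.24 and bHLH3 0.06. Of these, bZIP5 (-0.62), HSF4.7b (-0.61) and bZIP7 (-0.56) were called without Actin12, and HSF1g (0.43) on the total.

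The split of 1 higher and 4 lower became 3 and 3 on the total of the target probes, 2 and 3 on the median of ratios, 2 and 4 without Tbp, and 1 and 8 without Actin12 among the references. These tests used limma on 3 cultures per line, and over 1 to 22 h Wt replicate 3 entered without a 1 h sample. CYCB1 lost its call without Wt replicate 1, where its difference was -0.70 (adjusted p = 0.113), and without Wt replicate 2 (-1.39, adjusted p = 0.121), as well as over 1 to 22 h, on the authors' values, the total or the median of ratios, with a pseudocount of 10, a minimum mean signal of 100, the background floor or no reference division, and Vdr lost it over 1 to 22 h (-0.71, adjusted p = 0.135). Low signals limit the sizes: dsCYC2 was at or below the highest Wt background in 17 of 26 Wt and 23 of 27 OE-1 samples and HSF3.3a in 18 and 7, and with signals raised to that background the differences were -0.88 for dsCYC2, 1.79 for HSF3.3a and -0.78 for Vdr, all still called. With signals raised and no reference division as well, HSF4.7b was called in place of CYCB1.

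Expression changed over the dark period in all 15 genes in Wt and in all 15 in OE-1 (limma F-test over 9 time points), and in 14 and 13 with the background floor and no reference division. The transgene probe, wholly within background in Wt, was also called there (same test, adjusted p = 0.0308), so low signals can give a call. Samples of a culture were treated as independent here and in the tests of single times and of 25 h against 1 h below. Adjusted p-values can therefore be too small. In Wt bZIP7, with every sample above background, spanned 7.11 on the log2 scale between its lowest mean at 1 h and its highest at 10 h (adjusted p = 3.76e-18), and HSF4.7b 6.22 between the same times (adjusted p = 1.93e-15). bHLH1b spanned 7.27 (adjusted p = 4.95e-19), from a mean signal of 33.8 at 1 h. The references fell in Wt between these times, and without the division the spans were 4.65, 3.78 and 4.88. The lowest Wt means of the Myb-family gene Myb1R (11.1), bHLH3 (7.50) and Vdr (2.21) lay within background, so their spans of 8.37, 7.77 and 6.89 are not ranked against the others. Of the 10 transcription factors, 8 had their lowest Wt mean at 1 or 4 h and their highest at 10, 13 or 16 h. The basic leucine zipper gene bZIP5 ran the other way, with Wt signal at 11827 ± 4159 (SD, n = 2) at 1 h, 106 ± 49.0 (SD, n = 3) at 13 h and 5879 ± 3735 (SD, n = 3) at 25 h.

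The cyclins CYCB1 and dsCYC2 were highest at 1 h in Wt and fell into background, with spans of 4.62 and 4.70. CYCH1 had a span of 1.71 in Wt (adjusted p = 0.0023) and 1.40 in OE-1 (adjusted p = 0.0097), sizes that depended on the scale. Without the division the same times differed by 0.023 and -0.16. CYCH1 was then still called over time in Wt (adjusted p = 0.0302) but not in OE-1 (adjusted p = 0.875). On the total these differences were -1.02 and 0.51, and on the median of ratios -1.76 and 0.34. On both scales CYCH1 was called over time in both lines (limma F-test, largest adjusted p = 5.97e-04). In OE-1 bHLH3 spanned 7.19 (adjusted p = 3.30e-17) and Por2 6.73 (adjusted p = 4.20e-13), both with low ends that reached background, and bHLH1b, above background in every OE-1 sample, 3.42.

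The line-by-time test, which asks whether the profile itself differs, was called in 12 of the 15 genes: 8 of the 10 transcription factors, 2 of the 3 cell cycle genes, Por2 and Vdr. The smallest adjusted p-values belonged to bHLH1b (4.06e-09), Myb1R (8.59e-09), HSF4.7b (1.68e-08), Vdr (5.38e-08), bZIP5 and bZIP7 (8.73e-06 each). Endogenous bHLH1a (adjusted p = 0.105), dsCYC2 (0.297) and HSF3.3a (0.664) were not called. All 15 were called with the background floor, 14 on the total of the target probes and 13 without OE-1 replicate 1. Samples raised to the floor differ only by the references, so calls gained with the floor can come from the division. With the floor and no reference division 11 were called, without endogenous bHLH1a, bHLH3, bZIP7 and CYCH1. Without the division alone bZIP7 and CYCH1 lost their calls, as did bHLH3, CYCH1 and Por2 on the median of ratios. HSF3.3a had a higher mean in OE-1 than in Wt at each of the 9 time points, except at 4 h when the values were not divided by the references (-0.11) or were scaled by the median of ratios (-0.58), and at 10 h with the background floor (-0.24). In simulated datasets this test called 9.56% of the unchanged genes and 16.0% of its calls were false, so its adjusted p-values are too small, and it called 9 of the 15 genes without Wt replicate 2 or without OE-1 replicate 2.

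**Figure D2:**
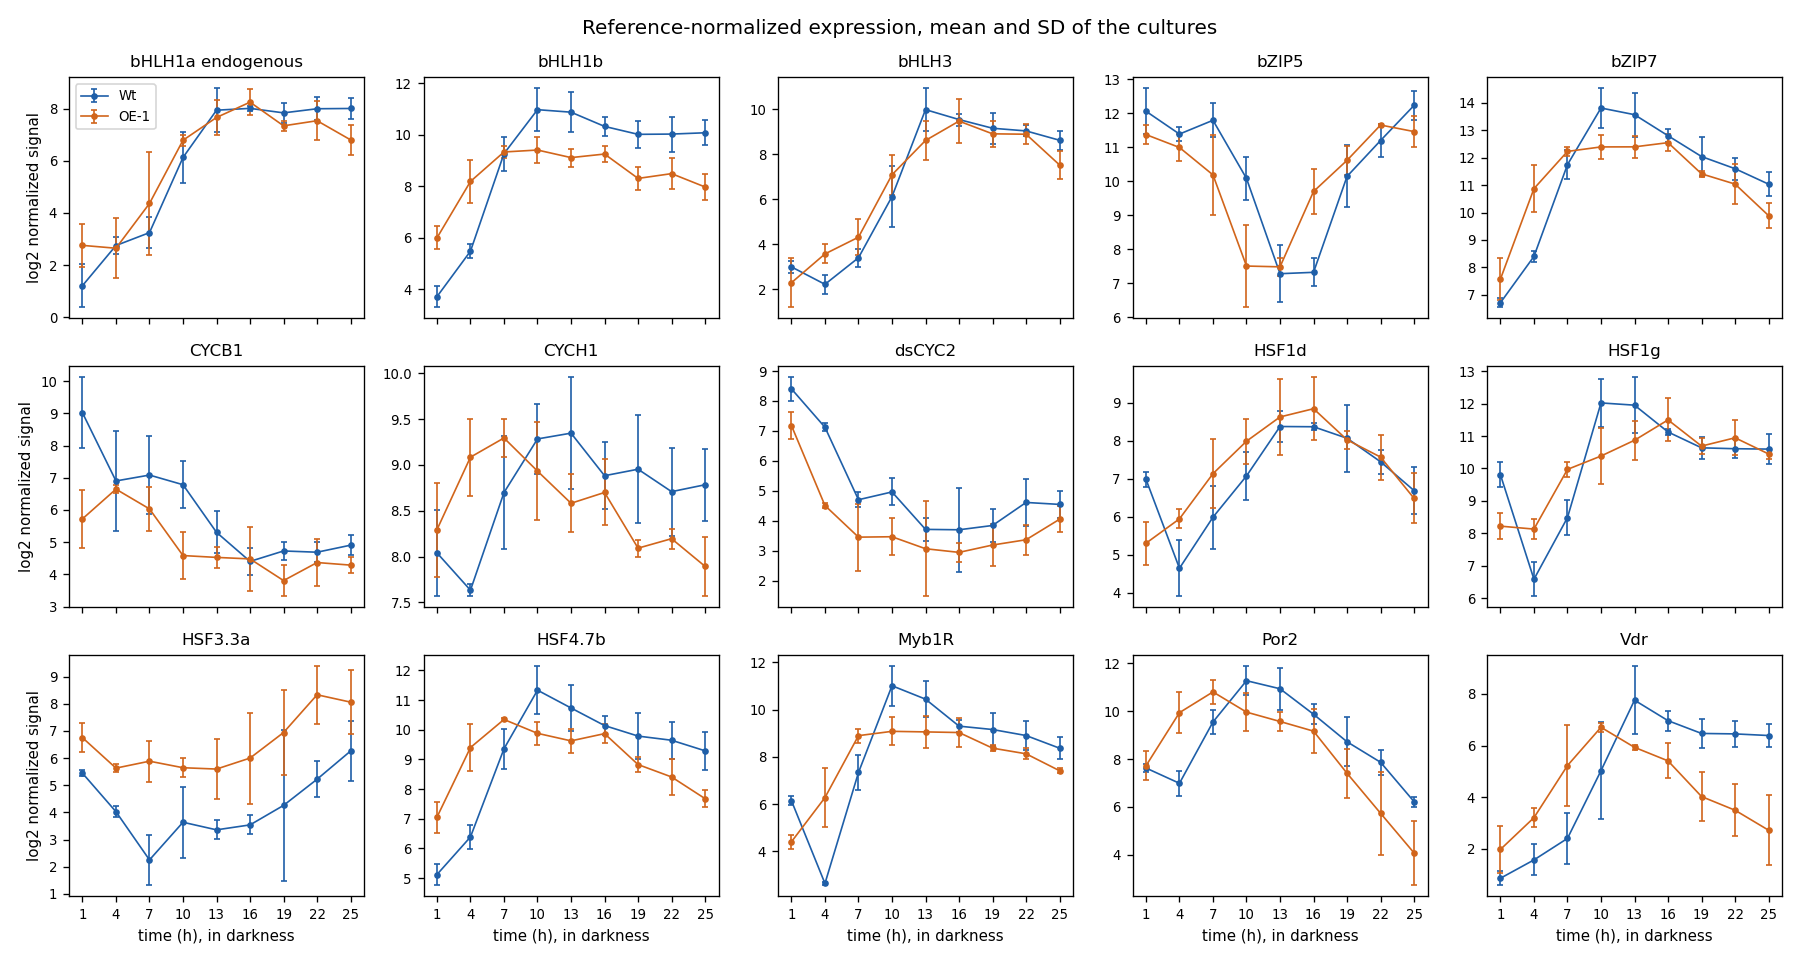
Log2 reference-normalized signal of the 15 genes against hours in darkness, as means with SD over cultures (n = 3, except n = 2 for Wt at 1 h). HSF3.3a has higher means in OE-1 at all 9 times, though not at 4 h without the reference division or at 10 h with the background floor, bHLH1b ends lower, and bZIP5 falls and recovers earlier in OE-1.

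Time point by time point, 48 of the 135 gene and time pairs differed, 19 higher and 29 lower in OE-1. The calls per time from 1 to 25 h numbered 6, 9, 5, 8, 5, 2, 3, 5 and 5. Every sample of both lines was above background in 30 of the 48 pairs, and 6 pairs had samples within it in both lines, among them Myb1R at 4 h, Vdr at 7 h and HSF3.3a at 7, 13 and 16 h. At 1 h CYCB1 was lower in OE-1 by a log2 difference of -3.29 (SE 0.66, adjusted p = 1.22e-04), with signals of 1664 ± 1300 (SD, n = 2) in Wt and 79.9 ± 52.5 (SD, n = 3) in OE-1. At 4 h HSF4.7b was higher by 3.01 (SE 0.47, adjusted p = 1.96e-06) and Myb1R by 3.64 (SE 0.49, adjusted p = 8.34e-08), or 2.37 with the background floor, and 0.66 (adjusted p = 0.212) with the floor and no reference division. bHLH1b started higher in OE-1, by 2.28 (SE 0.53) at 1 h, or 2.10 with the floor, and 2.71 (SE 0.47, adjusted p = 1.32e-05) at 4 h, and ended lower, by -2.11 (SE 0.47, adjusted p = 4.55e-04) at 25 h. Vdr was lower at 25 h by -3.67 (SE 0.72, adjusted p = 8.45e-05), or -1.93 with the floor, since OE-1 was within background there. Its value of 2.82 (SE 0.72) at 7 h compared signals within background in all but 1 of the 6 cultures. bZIP5 was lower by -2.57 (SE 0.52, adjusted p = 1.37e-04) at 10 h and higher by 2.38 (SE 0.52) at 16 h.

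Further differences were dsCYC2 at 4 h, at -2.61 (SE 0.57), or -1.38 with the floor, since all 3 OE-1 cultures were within background, and Por2 at 4 h, at 2.95 (SE 0.65). Por2 at 25 h had -2.14 (SE 0.65), or -1.42 (adjusted p = 0.032) with the floor and -0.96 (adjusted p = 0.124) with the floor and no division, with 1 of 3 OE-1 cultures above background. HSF3.3a was called at 7, 13, 16, 19 and 22 h, by 2.24 to 3.63, and no call was made at 1, 4, 10 or 25 h. At 19 h Wt replicate 1 read 217, above OE-1 replicates 1 and 2 (44.2 and 132), so the lines overlapped. That Wt sample also read 3593 for bZIP5, against 665 and 684 in the other Wt cultures. At 7 h the HSF3.3a signal in Wt was 5.0 ± 5.31 (SD, n = 3), within the background. With the background floor the differences at 7, 13 and 19 h became 1.12 (adjusted p = 0.127), 0.031 (adjusted p = 0.958) and 1.06 (adjusted p = 0.148), no longer called, while those at 4 h (1.63, adjusted p = 0.0251), 16 h (1.44, adjusted p = 0.0455), 22 h (2.84, adjusted p = 1.25e-04) and 25 h (1.76, adjusted p = 0.0151) were. Where both lines lie at the floor only the references differ, and with the floor and no division the calls were those at 22 h (3.19, adjusted p = 3.54e-04) and 25 h (2.24, adjusted p = 0.0108).

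The reference genes moved too, and this sets the scale of each time point. Rps signal in Wt went from 5983 at 1 h to 358 at 10 h, against 2015 and 751 in OE-1, and Tbp from 287 to 32.9, against 168 and 75.1. Actin12 stayed at or below the highest Wt background in 52 of the 53 samples, and Tbp did in 3 of the 26 Wt samples. The log2 reference factor of OE-1 relative to Wt was -0.99 at 1 h, -1.78 at 4 h, -0.84 at 7 h and 0.65 at 10 and 13 h. As a result the median difference of the 15 genes at 4 h was 1.54 with division by the references, 0.94 with Actin12 left out of them and -0.16 without the division. At 10 h it was -1.42 with and -0.77 without, and at 1 h 0.09 with and -0.90 without.

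Of the 48 called pairs, 22 were called with the same sign under all 7 scalings tried, among them HSF4.7b at 4 h, with 1.25 without the division and 0.77 on the median of ratios. Some of the scalings share reference genes, and none tests signals within background. The 22 include HSF3.3a at 7 and 19 h, Myb1R at 4 h, Vdr at 7 h and Por2 at 25 h. These lost their calls with the floor and no division. In all, 45 of the 48 kept their sign under each scaling, and the 3 that turned sign were CYCH1, HSF1d and HSF1g at 4 h. CYCH1 went from 1.45 (adjusted p = 0.0034) to -0.80 on the median of ratios, called in the opposite direction (adjusted p = 0.0219). At 4 h Por2 (1.18, adjusted p = 0.115) and bZIP7 (0.70, adjusted p = 0.117) lost their calls without the division, and both, with bHLH1b (0.48, adjusted p = 0.173), lost them on the median of ratios. Without the division CYCB1 at 1 h had -4.29, bHLH1b at 25 h -1.63 and bZIP5 -1.93 at 10 h and 2.10 at 16 h. With the floor and no division dsCYC2 at 4 h had -3.14 and Vdr at 25 h -1.47, both called, and 29 of the 48 pairs kept their calls. The split of calls moved with the scaling, to 14 higher and 31 lower without the division, 17 and 48 without Actin12, 20 and 18 without Rps, 23 and 17 without Tbp and 32 and 22 on the total of the target probes.

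**Figure D3:**
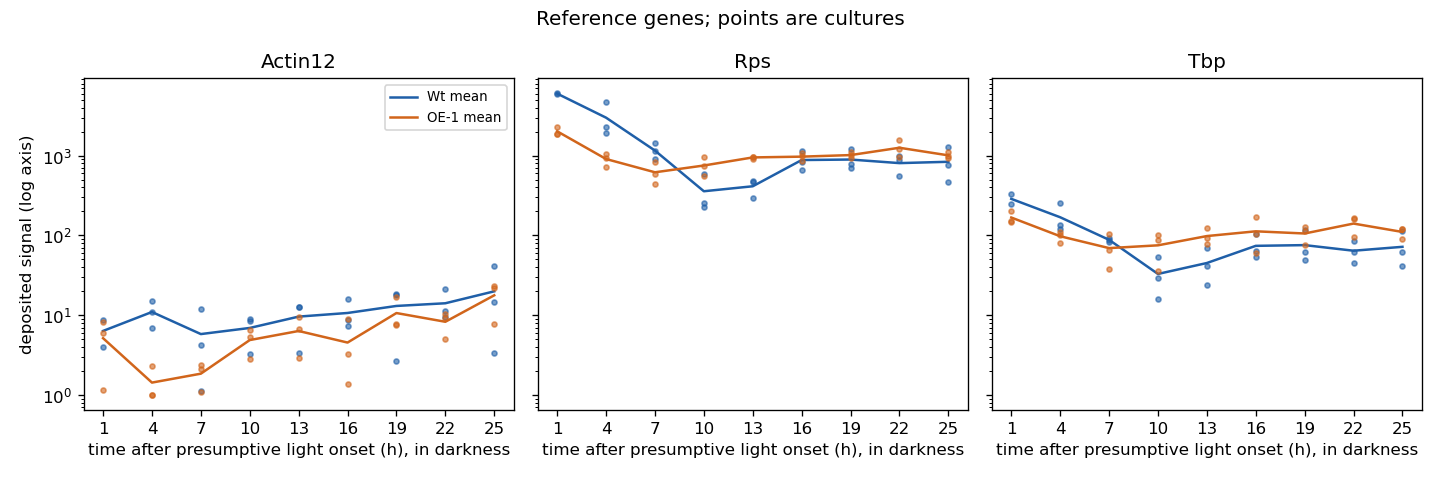
Signal of the 3 reference genes on a log axis against hours in darkness, with points for cultures and lines for group means. Mean Rps and Tbp are higher in Wt at 1 h and reach 358 and 32.9 at 10 h, below OE-1, and Actin12 lies near background.

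A cosine of 24 h was fitted to give each gene an amplitude and a peak time, with the limit that 1 cycle cannot tell a rhythm from a single rise and fall. The cosine was called in all 15 genes in both lines, and in 12 in OE-1 with the background floor and no reference division. In Wt 11 genes peaked between 12.5 and 17.3 h. Amplitudes on the log2 scale were 3.60 for bHLH3 (SE 0.46, peak 17.3 h), 2.70 for endogenous bHLH1a (SE 0.45, peak 17.2 h) and 2.68 for Vdr (SE 0.38, peak 16.7 h). The low ends of these 3 lay within background, and with the floor they were 2.76, 1.84 and 1.37. HSF3.3a peaked at 22.9 h, bZIP5 at 2.59 h, dsCYC2 at 3.50 h and CYCB1 at 5.86 h. CYCH1 had 0.53 (SE 0.16) and was not called in Wt without Rps, without Tbp or without Wt replicate 2. bHLH1b in OE-1 lost its cosine call with any OE-1 culture left out (adjusted p = 0.061 to 0.155), on the total (0.141), on the median of ratios (0.242) and without 1 h (0.107). CYCB1, CYCH1 and dsCYC2 in OE-1, HSF1g in Wt and, with the background floor, HSF3.3a in Wt each lost theirs in at least 1 alternative.

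The cosine differed between the lines in 4 genes. bZIP5 peaked at 23.8 h in OE-1, 2.80 h earlier than in Wt (adjusted p = 0.0013), and Vdr at 12.1 h, 4.66 h earlier (adjusted p = 2.59e-04). Por2 peaked 2.47 h earlier and CYCH1 5.58 h earlier (adjusted p = 0.0365 each). Peak times were earlier in OE-1 for 14 of the 15 genes, the exception being HSF1g, with a median difference of -1.62 h over the panel. Vdr alone was called without OE-1 replicate 3, and 2 genes, bZIP5 and Vdr, without Wt replicate 1, Wt replicate 2 or OE-1 replicate 2, or without the reference division; with a linear trend they were bHLH1b and bZIP5. CYCH1 peaked 4.27 h later in OE-1, not earlier, on the total of the target probes (adjusted p = 0.0605). Its mean signals in OE-1 ran only from 321 to 422. Without the division its OE-1 amplitude was 0.073 and its cosine was not called there (limma F-test, adjusted p = 0.815). Its OE-1 peak time therefore depends on the references. In simulated datasets the test of a cosine difference called 12.6% of the unchanged genes and 17.1% of its calls were false, so its adjusted p-values are too small.

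Fitted culture by culture over 4 to 25 h, the amplitude was lower in OE-1 for 13 of the 15 genes. Myb1R, whose Wt signals at 4 h lay within background, went from 2.45 ± 0.35 to 1.10 ± 0.21 (SD, n = 3 each), bHLH1b from 1.55 ± 0.23 to 0.72 ± 0.40 and HSF1g from 1.78 ± 0.30 to 1.10 ± 0.17. Por2 went the other way, from 2.32 ± 0.34 to 2.65 ± 0.78, as did CYCH1, from 0.51 ± 0.27 to 0.59 ± 0.12. The exact two-sided permutation test gave p = 0.1 for Myb1R, bHLH1b, bZIP7 and HSF1g, the smallest value that 3 against 3 allows, and the adjusted value was 0.283, so no single gene is shown to differ in amplitude. The amplitude was lower in OE-1 for 11 genes on the total and for 10 without the division or on the median of ratios, where HSF1g was higher in OE-1, with 1.44 and 1.52 without the division and 0.70 and 1.04 on the median of ratios.

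The samples at 25 h and 1 h are the same clock time 24 h apart, and they show how far each gene returned to its start. In Wt 9 of the 15 genes differed, 7 higher and 2 lower at 25 h. bZIP7 was higher by 4.33 (SE 0.51, adjusted p = 2.74e-10) and HSF4.7b by 4.17 (SE 0.53, adjusted p = 1.19e-09). Without the reference division these were 3.02 and 2.88. For 4 genes Wt signals at 1 h lay wholly or partly within background: Vdr had 5.53 (SE 0.80, adjusted p = 3.34e-08) or 2.72 with the floor, endogenous bHLH1a 6.80 (SE 0.69, adjusted p = 5.72e-12) or 4.34, bHLH1b 6.37 (SE 0.53, adjusted p = 1.38e-14) or 6.19, and bHLH3 5.64 (SE 0.65, adjusted p = 1.88e-10) or 4.95. The floor alone keeps the fall of the references: the Wt transgene probe, raised to a single value in every sample, still had 1.26. With the floor and no reference division these 4 genes had 1.47, 3.09, 4.94 and 3.71, all still called. The cyclins CYCB1 and dsCYC2, mostly within background at 25 h, had -4.11 (SE 0.66) and -3.86 (SE 0.64). With the floor they had -3.63 and -3.18, and with the floor and no division -4.95 and -4.49. bZIP5 had 0.17 (SE 0.58) in Wt and 0.09 (SE 0.52) in OE-1, or -1.15 (adjusted p = 0.067) and 0.24 with the floor and no reference division. In OE-1 10 genes differed, 7 higher and 3 lower, the latter being CYCB1, dsCYC2 and Por2, which had -3.64 (SE 0.65, adjusted p = 3.98e-06), or -2.92 with the floor.

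The change from 1 to 25 h differed between the lines in 6 genes. It was smaller or absent in OE-1 for bHLH1b (difference -4.39, SE 0.71, adjusted p = 8.08e-07), HSF4.7b (-3.55, SE 0.71, adjusted p = 3.61e-05), Vdr (-4.78, SE 1.07, adjusted p = 1.88e-04), endogenous bHLH1a (-2.75, SE 0.92) and bZIP7 (-2.01, SE 0.69). CYCB1 fell less in OE-1, with a difference of 2.68 (SE 0.89, adjusted p = 0.0112). Wt has 2 samples at 1 h. Signals of Vdr, endogenous bHLH1a and bHLH3 at 1 h lay within background in both lines. With the background floor their differences were -2.86 (adjusted p = 2.86e-04), -2.14 (adjusted p = 0.0052) and -2.04 (adjusted p = 0.0153), the last a call gained from -0.40. With the floor and no reference division they were -1.47 (adjusted p = 0.0075), -0.73 (adjusted p = 0.256) and -0.62 (adjusted p = 0.399). Without the reference division the differences were -2.99 for bHLH1b, -2.10 for HSF4.7b, -3.95 for Vdr and 4.12 for CYCB1, all called, while endogenous bHLH1a (-1.71, adjusted p = 0.122) and bZIP7 (-0.55, adjusted p = 0.346) lost their calls. With cultures left out, CYCB1 lost its call without Wt replicate 1 (1.77) or OE-1 replicate 2 (2.12), endogenous bHLH1a without Wt replicate 2 (-2.40) or OE-1 replicate 3 (-1.96), and bZIP7 without Wt replicate 1 (-1.82) or OE-1 replicate 3 (-1.31). Without Wt replicate 1 or 2 a lone Wt sample remained at 1 h, and the fit assumes that it varies like the other groups. The split of these calls was 1 higher and 5 lower in OE-1 with the references, 4 and 3 without the division, 4 and 7 on the total of the target probes and 4 and 4 on the median of ratios. In Wt alone the split of 7 higher and 2 lower became 6 and 4 without the division, 7 and 4 on the total, 7 and 6 on the median of ratios and 6 and 3 without Rps. In OE-1 alone 7 and 3 became 9 and 2 without Actin12, 8 and 2 without the division and 6 and 4 on the total or the median of ratios.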

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

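The tests of the reference division, of background, and of single cultures for HSF3.3a and for the peak times were chosen after the results they measure, or closely related values, had been seen.

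A test of the difference between the lines marked the following results. The change from 1 to 25 h differed between the lines for 8 probes, on the log2 scale as OE-1 minus Wt. The values were -2.75 for endogenous bHLH1a, -4.39 for bHLH1b, -2.01 for bZIP7, 2.68 for CYCB1, -3.55 for HSF4.7b, -4.78 for Vdr, -7.37 for bHLH1a total and -7.85 for the bHLH1a transgene. The last value includes a rise of 2.79 in Wt (limma, adjusted p = 0.0024), which lacks the transgene, so signals within background can give a call. With the floor and no reference division the differences were -5.16 for bHLH1a total and -3.93 for the transgene. Cosines differed for 6 probes. For bHLH1a total and the transgene the amplitude differed by -1.92 and 2.25. The peak time differed by -2.80 h for bZIP5, -5.58 h for CYCH1, -2.47 h for Por2 and -4.66 h for Vdr. Without the reference division CYCH1 had no called cosine in OE-1, so its peak difference depends on the references.

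Most genes were higher in OE-1 at 4 h, with a median difference of 1.54 over the 15 genes. The pattern did not rest on a single culture, since the lowest median with each culture left out was 1.38, without OE-1 replicate 3. Without division by the reference genes the median was -0.16, so the general shift is consistent with the higher reference signals of Wt at that time. Whether those reflect RNA input or expression of the references is open, since the input is not given in the sources used here, and a difference between the lines stays open too.

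HSF3.3a was higher in OE-1 over 4 to 25 h by 2.22. Neither the reference genes nor a single culture accounts for it: without the division it was 2.07, and the lowest value with each culture left out was 1.62, without OE-1 replicate 3, called in each case. Background in Wt does not account for the whole of it either, since with the floor the difference was 1.79, and 1.63 with the floor and no division, both still called, although at 7 h the floor reduced 3.63 to 1.12 and ended the call. With the floor and no division single times were called at 22 and 25 h only. A biological difference between the lines may underlie the rest, as a hypothesis, and a difference of this single transgenic line unrelated to bHLH1a was not tested.

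Peaks were earlier in OE-1 in 14 of the 15 genes, with a median of -1.62 h. Without the reference division the median was -1.39 h, but the culture medians then were 0.18, -1.30 and -2.13 h in OE-1 and 0.25, 0.59 and 0.01 h in Wt, so OE-1 replicate 1 lay among the Wt cultures. With the division they were -0.82, -1.22 and -2.43 h against 0.68, -0.02 and 0.24 h. With each culture left out the value nearest 0 was -1.02 h, without OE-1 replicate 3, and other splits of the cultures gave medians from -1.09 to 1.35 h. A part of the division, a single culture and a biological shift, which may be present, therefore all stay open.

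For comparisons of the lines, the 6 cultures make 10 splits of 3 against 3, too few for a share under 0.05. The real split, 1 of the 10, called 5 genes for level, 12 for time course, 48 pairs, 4 for cosine and 6 for the 25 h against 1 h change, and the highest of the other splits was 0 for each of these. In OE-1 alone, 25 h against 1 h called 10 genes, and the highest of the other splits of the 6 samples was 3, again too few splits to decide. With time labels shuffled within a line, 1 of 100 groupings, the real one, reached 15 genes. The highest other was 14 for the time course and 14 for the cosine in Wt, and 13 and 4 in OE-1. Chance can be excluded only for labels that could be exchanged freely between samples, since the count cannot exceed 15 and shuffling does not keep the relation of neighbouring samples of a culture.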

How the results depend on the processing

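Scaling without the reference genes, the background floor, both together and their effects were chosen after the data were seen. Count-based tests and TMM factors were not run because the signals are not counts, nor was subtraction of negative controls, since no such probes are in the tables used. The minimum mean signal of 20 removed no probe and tests nothing. Over the summary results, 269 values under alternatives kept their direction and side of the threshold, or stayed within 1.5 times the main count, 14 counts moved further and 5 values passed the threshold. Over single genes, 1663 stayed alike, 92 lost a call, 28 gained one and 21 turned sign. Signals at background limit dsCYC2, HSF3.3a, CYCB1 and Vdr most.

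The bHLH1a total level (0.49) was called with 0.68 (adjusted p = 0.0013) on the total of the target probes, 0.60 (0.010) on the median of ratios, 0.75 (0.0404) without Tbp, 0.97 (0.0083) as a mean of log2 values and 1.09 (0.0179) over 1 to 22 h, and with a culture left out it ranged from 0.36 to 0.64. In all results over 1 to 22 h Wt replicate 3 has no 1 h sample, so its times differ from those of the other cultures. The 5 genes called in level became 9 without Actin12, 3 over 1 to 22 h, and 2 with a minimum mean signal of 100, which removed dsCYC2 and Vdr from the test and where CYCB1 was not called (-1.29, adjusted p = 0.112), with 4 to 6 when a culture was left out. The 4 cosine differences became 2 without Rps, without Tbp, with a 21 h period, with a linear trend and without the division, with or without the floor, and ranged from 1 to 5 with a culture left out. The 6 differences of 25 h against 1 h became 11 on the total of the target probes, and 4 to 7 with a culture left out, where without Wt replicate 1 or 2 a lone Wt sample at 1 h is assumed to vary like the other groups. For the other counts, called pairs ranged from 32 to 52 and differing time courses from 9 to 13 with a culture left out.

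Level differences turned sign for endogenous bHLH1a with the authors' values (-0.25), without Actin12 (-0.15), as a mean of log2 values (-0.066) and without the division (-0.041, or -0.038 with the floor as well). They did for bHLH3 with the authors' values (-0.44), without Actin12 (-0.21), without the division, with or without the floor (-0.098), without Wt replicate 1 (-0.10) and without OE-1 replicate 3 (-0.18), where leaving out a culture gave -0.18 to 0.22, and for HSF1g with the authors' values (-0.31) and without Actin12 (-0.027). CYCH1 did so on the total (0.068), without Tbp (0.14) and over 1 to 22 h (0.045), and Por2 without Tbp (0.023). None of these level differences was called in the main setting. CYCH1 at 4 h, called with 1.45, had -0.80 on the median of ratios, called in the opposite direction, and -0.32 without the division, with or without the floor, and its peak came 4.27 h later on the total. The cause of these changes was not tested.

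The replicate numbers do not pair the lines: same-numbered cultures had correlations of -0.09, -0.25 and 0.28 between the lines, and not every culture correlated best with its own number. Within a culture, neighbouring times had correlations of 0.26 to 0.73, and all pairs of times 0.05 to 0.28. Fits that treat the samples of a culture as independent can therefore give p-values that are too small. With the replicate number as a replicate block, 50 pairs, 5 levels, 12 time courses, 4 cosines and 7 changes from 1 to 25 h differed. With the culture as a replicate block, 12 time courses, 4 cosines and 8 changes from 1 to 25 h differed.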

Other observations

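Signals of the transgene probe fell at different rates in the 3 OE-1 cultures. Between 1 and 10 h the signal went from 786 to 11.1 in replicate 1, from 262 to 41.0 in replicate 2 and from 597 to 132 in replicate 3. In Wt replicate 2 at 7 h the total probe read 199 and the transgene probe 31.6, while the other Wt cultures read 11.3 and 28.7 for total and 2.83 and 5.20 for the transgene. Wt replicate 1 had a transgene signal of 30.0 at 19 h. The value of 31.6 sets the background floor used above.

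A hypothesis was that the HSF3.3a excess in OE-1 follows the transgene transcript and ends when that is back at the Wt level, a test chosen after the values were seen. Over 19, 22 and 25 h the mean transgene difference was 0.38 on the log2 scale, against 5.44 over 1 to 10 h. The HSF3.3a difference was 2.53 over the late times and 2.14 over the early ones, and with the background floor and no reference division it was called at 22 h (3.19) and 25 h (2.24), which argues against an excess that ends with the transcript. In that same setting the early differences were 0.33 at 1 h, -0.09 at 4 h, 0.30 at 7 h and 0.40 at 10 h, none of them called. The early value of 2.14 thus rests on signals within background and on the references, and an early excess while the transgene was high is not shown. Protein was not measured, so a lasting effect of bHLH1a protein could remain, as could a difference between the lines that is independent of the transgene.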
